A study of Homo sapiens with 16 samples.

How the data were processed

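Gene expression was measured with Affymetrix HG-U133A GeneChips, 1-colour arrays on which each transcript is read by a probe set of short oligonucleotides near its 3' end. There were 16 arrays: 4 anaplastic large cell lymphoma (ALCL) lines and 4 T-cell leukaemia or lymphoma lines, each hybridised once untreated and once after treatment. Per the labels' protocols, treatment was 1 µM 5-aza-2'-deoxycytidine for 6 days with 625 nM trichostatin A added for the last 24 hours, and biotin-labelled target was made from total RNA.

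The deposited values are log2 expression summaries, made with RMA (robust multi-array average) in R 2.10.1 per the submitters' processing notes. The probe set definitions and any filter behind the deposited log2 values are not given in the sources used here. The values ran from 3.36 to 14.4. The arrays had medians between 6.78 and 6.96, but their values did not share 1 distribution. RMA normalizes single probes before it summarises them into probe sets, so this does not tell whether the arrays were normalized as 1 set. Scanner files and detection calls were not used here, so no statement is made on whether a gene was above background.

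The table listed 22283 probe sets. In the platform's annotation, 19065 had 1 gene symbol, 1043 had several and 2107 had none listed, and 68 were control probe sets. Symbols were taken from that annotation, and 11954 of the 11963 genes tested were found in a table of human RefSeq genes. For each gene the probe set with the highest mean over the 16 arrays was used, which mattered for 4310 genes with several probe sets. No genome was used here, so no coordinates are given.

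Groups came from the sample labels, which name the cell line and the treatment. The same cell line appears untreated and treated, so each line served as its own control. The pairing was checked by correlating, across genes, the deviations of a line's untreated and treated arrays from their group means. The correlation was between 0.33 and 0.643 in the 8 lines. The highest with another line of the same type was 0.399, for Molt-3 (0.413 with itself), so this check barely tells Molt-3 from Molt-4, whose untreated array was closer to the treated Molt-3 array (r = 0.9246) than that of Molt-3 was (0.9199).

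Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 11963 genes. A gene is called, or said to rise, fall or differ, at an adjusted p below 0.05. The treatment effect in each cell type and the difference between the 2 effects (the interaction) came from 1 fit of all 16 arrays with the cell line as a block, which left 6 residual degrees of freedom. The 3 comparisons between cell types used 8 arrays each. All adjusted p values of genes are from limma. The value after ± beside a log2 difference is its standard error from that fit.

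Whole lists of genes, 35 in all, were fixed before the data were examined and tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the lists. Each was tested again with a correlation estimated from the data and with fry, and each list's median was set among 10000 random lists matched on untreated level. Beside each list, the numbers of genes called over all genes come first and those adjusted over the list alone second. Movement of the T-cell lines along the starting difference was measured by the slope, through 0, of the treatment change on that difference. It was repeated with the T-cell lines split 2 and 2 so that no array was shared, and set against 100 simulations of unchanged lines. These added noise to the measured untreated values, so they were noisier than the data. They called 627 genes between untreated cell types in the mean, against 1048 in the data.

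Genes are named by a rule fixed before the data were examined. In each comparison these were the 8 highest and 8 lowest differences among called genes that moved the same way in all 4 lines, or, between cell types, whose 4 and 4 values did not overlap. To these were added up to 4 members with the smallest adjusted p of each list described, and ID2, LGALS1, JUN, CLU, TNFRSF8, ALK, CD3E, LCK, ZAP70, DNMT1, HDAC1 and CDKN1A in any comparison, some of them chosen from knowledge of this field and this study. Not every gene that the rule picked is named in every comparison.

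The scripts were tested on simulated data with 11963 genes in 10 simulations. Of genes changed 2-fold, 83.6% were called for the treatment effect in T-cell lines, 83.3% in ALCL lines, 37.5% for the interaction and 61.6% between untreated cell types. For genes changed 4-fold the shares were 99.8%, 99.5%, 97.9% and 90.2%. A slope of 0.3 put into the data was found as 0.306.

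Alternatives fixed before the data were examined were a fit without the line block, 1 cell type alone, line as a random block, the mean of a gene's probe sets, each probe set by itself, a filter removing the lowest 40% of genes, 4 other scalings of the arrays, a trended and robust prior, array weights, a 2-fold minimum, Molt-3 and Molt-4 as 1 replicate, and each line left out in turn. After the data were examined, a scaling to 1 mean and standard deviation (SD), fits without JB6 and Molt-4, fits within lines of like ribosomal RNA signal, and covariates for RNA quality and ribosomal signal were added. Their effects are given in the closing section. Figures were drawn with matplotlib 3.10.9.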

Results

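Expression profiles were available for 8 human cell lines before and after an epigenetic treatment. FE-PD, JB6, SU-DHL-1 and Karpas 299 come from anaplastic large cell lymphoma (ALCL), a lymphoma of T-cell origin that carries CD30 and often an ALK fusion and has lost much of the T-cell programme. CCRF-CEM, Jurkat, Molt-3 and Molt-4 come from T-cell leukaemia and still carry that programme. The treatment joined 5-aza-2'-deoxycytidine, which blocks DNA methyltransferases, with trichostatin A, which blocks histone deacetylases. There were 4 groups of n = 4 arrays, 1 per line and condition. The p-values therefore measure the spread between lines, and Molt-3 and Molt-4, known to derive from 1 patient, correlated at 0.995 when untreated. Per the series title, the question was whether histone acetylation and DNA demethylation of T-cell lines call up an ALCL-like expression pattern.

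Treated arrays differed from untreated ones in ways that no gene group defines. The SD of the values on an array was 1.89 ± 0.0351 (SD, n = 8) untreated and 1.73 ± 0.088 treated. It was lower on the treated array in 8 of 8 lines (change -0.155 ± 0.0933, exact sign-flip permutation p = 0.00781, the smallest possible, adjusted 0.0137). The 3' minus 5' signal of ACTB, a measure of RNA or target length, rose by 0.60 ± 0.39 (SD) in the mean and in 7 of 8 lines (exact p = 0.0156, adjusted 0.0218). The 28S ribosomal RNA control stood between 12.05 and 14.26 on 5 treated arrays (FE-PD, JB6, SU-DHL-1, Molt-3 and Molt-4). It stayed near its untreated mean of 7.20 on those of Karpas 299, CCRF-CEM and Jurkat. The hybridisation spikes, added to each sample, were higher on treated arrays by 0.64 ± 0.67 (SD, 7 of 8 lines, exact p = 0.0391, adjusted 0.0391). List medians are therefore also given within the 2 T-cell lines without and the 2 with the 28S rise, and in the 1 and 3 such ALCL lines.

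**Figure D1:**
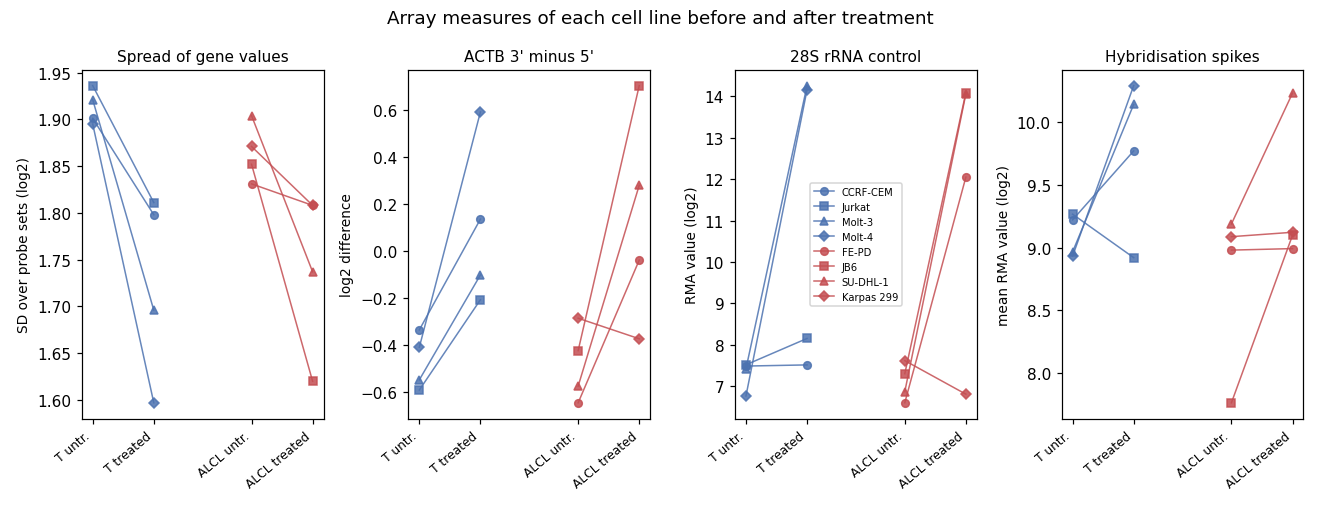
Each panel plots 1 measure of an array (y axis, log2) for the 4 T-cell lines (blue) and the 4 ALCL lines (red), with a line joining a cell line's untreated and treated array. The SD of the values is lower on every treated array, and the 28S control is above 12 on 5 of the 8 treated arrays.

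Before treatment, T-cell receptor genes were lower in ALCL lines than in T-cell lines, and cytotoxic granule genes were higher (adjusted p = 0.0665 for the latter with an estimated correlation). CLU, a secreted chaperone, was 107-fold higher in ALCL lines (log2 difference 6.75 ± 0.25, n = 4 and 4). The cytotoxic granule genes GZMB and PRF1 were 91.5-fold and 69.4-fold higher. SERPINA1, a protease inhibitor, was 76.8-fold higher and LGALS1, the lectin galectin-1, 42.3-fold, with adjusted p values of 3.51e-05 and 0.00091. LCK, the kinase that starts T-cell receptor signalling, was 52.1-fold lower (-5.70 ± 0.30, adjusted p = 3.51e-05). The membrane protein TSPAN7 and the growth factor binding protein IGFBP2 were 36-fold and 32.9-fold lower. In all, 380 genes were higher and 668 lower in ALCL lines, and 599 of the 1048 differed at least 2-fold.

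Of 30 measured ALCL-associated genes, 20 were higher in ALCL lines and 0 lower (23 and 0 adjusted over the list alone; median 2.09, adjusted p = 1.89e-20, and adjusted p = 0.00119 with an estimated correlation). The list was drawn up from known markers of this lymphoma, some of them described in these lines, so its count is not independent evidence. Its members included TNFRSF8, which encodes CD30 (3.66 ± 0.31), the inhibitor of metalloproteases TIMP1 (5.29 ± 0.70), the decoy receptor IL1R2 (5.13 ± 0.19) and JUNB (3.49 ± 0.17). The helix-loop-helix inhibitor ID2 was higher by 4.20 ± 0.99 (adjusted p = 0.0384), a call lost in 12 of 22 alternatives (adjusted p up to 0.225), among them when any 1 line other than FE-PD was left out, with adjusted p between 0.0622 (SU-DHL-1) and 0.104 (Molt-4). JUN differed by 2.27 ± 0.42 (adjusted p = 0.0158), a call lost in 5 of 22 alternatives (up to 0.128), among them without Molt-3 (0.0531) or Molt-4 (0.0514). ALK was not called, with a difference of 3.27 ± 0.93 (adjusted p = 0.0673), which was 4.32 (adjusted p = 0.000182) without FE-PD, an ALK-negative line. GAS1 (5.88 ± 0.41) and TNS3 (5.27 ± 0.50) were also among the 8 largest positive differences.

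Genes of the T-cell receptor and its proximal signalling were lower in ALCL lines, 15 of 23 measured and 0 higher (16 and 0 adjusted over the list alone; median -1.84, adjusted p = 4.75e-12, and adjusted p = 0.0292 with an estimated correlation). CD3E (-3.15 ± 0.17) and CD3G (-3.07 ± 0.17), invariant chains of the receptor, and TRBC1 (-4.49 ± 0.91), a constant region of its beta chain, were lower, the last a call lost in 7 of 22 alternatives (adjusted p up to 0.128), among them without Jurkat (0.0504), Molt-3 (0.0711) or Molt-4 (0.0694). Of 27 T-cell surface markers 10 were lower and 0 higher (14 and 0 adjusted over the list alone; median -0.949, adjusted p = 1.27e-06, and adjusted p = 0.0738 with an estimated correlation). CD7 (-2.91 ± 0.28) and CD1A (-2.10 ± 0.23) were among them. Of 24 T-lineage transcription factors 11 were lower and 0 higher (13 and 2 adjusted over the list alone; median -1.06, adjusted p = 6.02e-06, and adjusted p = 0.0292 with an estimated correlation). BCL11B (-3.96 ± 0.37), TOX (-4.37 ± 0.43) and GATA3 (-3.01 ± 0.40), which guide T-cell development, were lower. ADA (-4.24 ± 0.39), which breaks down adenosine, the membrane protein ITM2A (-4.50 ± 0.43) and RCBTB2 (-4.63 ± 0.73) were lower too.

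Cytotoxic granule genes were higher in ALCL lines as a list, 4 of 14 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.905, adjusted p = 0.000115, and adjusted p = 0.0665 with an estimated correlation). SRGN, the granule proteoglycan, was higher by 3.53 ± 0.42. AP-1 and immediate early genes counted 7 higher and 1 lower of 22 (11 and 1 adjusted over the list alone; median 0.581, adjusted p = 5.38e-06, and adjusted p = 0.0292 with an estimated correlation). BHLHE40, a transcriptional repressor, was higher by 4.38 ± 0.51. Hypoxia and glycolysis genes counted 9 higher and 0 lower of 26 (12 and 0 adjusted over the list alone; median 0.584, adjusted p = 3.13e-06, and adjusted p = 0.0292 with an estimated correlation). The glucose transporter SLC2A3 was higher by 3.12 ± 0.25 and the glycolytic regulator PFKFB3 by 3.08 ± 0.29. Centring on the hybridisation spikes moved the median difference of all genes from 0.04 to 0.38 and the share of calls higher in ALCL lines from 36.3% to 75%. None of these lists changed sign under it. Leaving out Molt-3 or Molt-4 lowered the count from 1048 to 455 or 476. The 3 lines without the 28S rise alone, where Karpas 299 is the 1 ALCL line and is assumed to vary like CCRF-CEM and Jurkat, gave 111 and the 5 with it 689, and without JB6 and Molt-4 there were 334.

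Markers of other cell types passed as lists before treatment as well, higher in ALCL lines with the preset correlation. These were mesenchymal and matrix genes (7 and 1 of 29, 7 and 2 adjusted over the list alone; median 0.227, adjusted p = 0.00125, and adjusted p = 0.209 with an estimated correlation), epithelial genes (1 and 0 of 20, 1 and 0 adjusted over the list alone; median 0.237, adjusted p = 0.00511, and adjusted p = 0.209 with an estimated correlation), myeloid markers (2 and 1 of 24, 3 and 1 adjusted over the list alone; median 0.173, adjusted p = 0.023, and adjusted p = 0.239 with an estimated correlation), NK-cell markers (1 and 0 of 13, 1 and 0 adjusted over the list alone; median 0.172, adjusted p = 0.0319, and adjusted p = 0.454 with an estimated correlation) and neuronal genes (2 and 0 of 31, 0 and 0 adjusted over the list alone; median 0.126, adjusted p = 0.0423, and adjusted p = 0.487 with an estimated correlation).

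**Figure D2:**
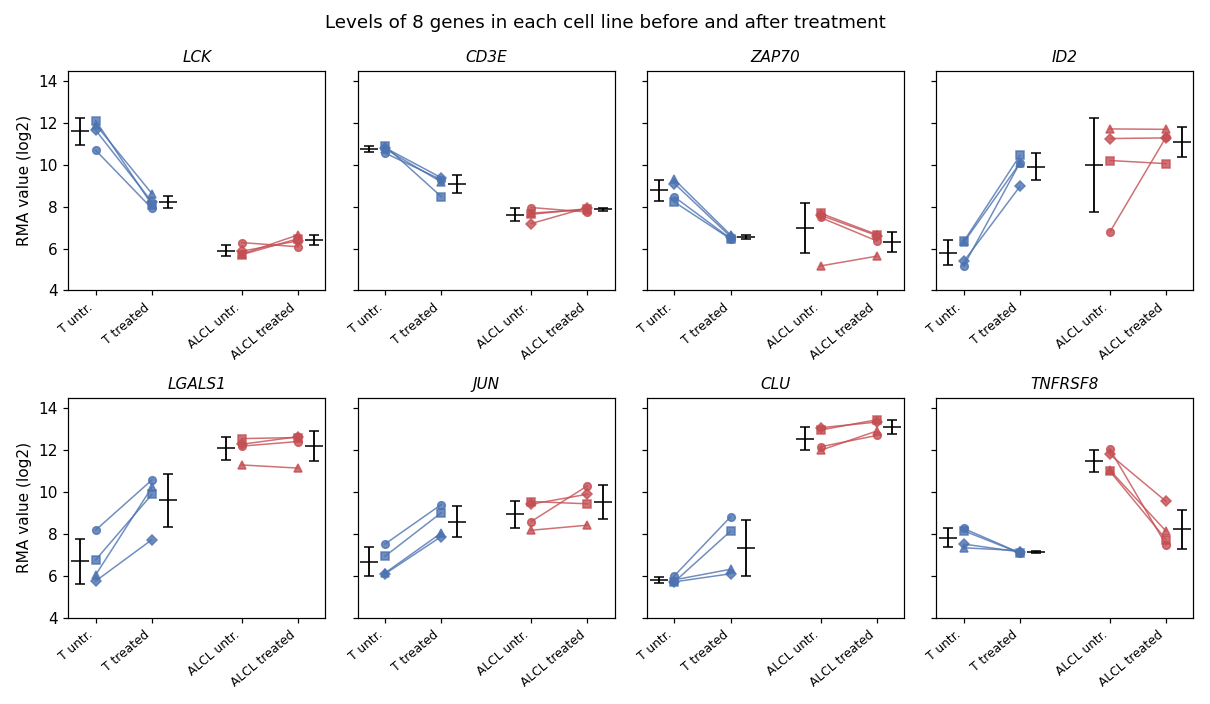
Levels (y axis, log2 RMA value) of 8 genes fixed in advance, in the 4 T-cell lines (blue) and 4 ALCL lines (red), with a line joining a cell line's untreated and treated array and bars for the mean and SD of each group. LCK fell from 11.60 to 8.22 in T-cell lines, and TNFRSF8 fell from 11.48 to 8.23 in ALCL lines.

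The next comparison asked what the treatment did in the T-cell lines. With the preset correlation, lists of T-cell receptor and cell-cycle genes fell, and lists of germline, neuronal and histone genes rose. None of the 35 lists was called with an estimated correlation (adjusted p = 0.104, 0.336, 0.212, 0.212 and 0.274 for these). LCK fell 10.4-fold, from 11.60 to 8.22 (-3.38 ± 0.22, n = 4, adjusted p = 2.79e-05), and TRAT1, a receptor-associated adaptor, 10.6-fold (-3.41 ± 0.16). TKTL1, a transketolase-like gene counted among the cancer-testis antigens, rose 24.9-fold (4.64 ± 0.40, adjusted p = 8.43e-05), and the dehydrogenase DHRS2 18.7-fold (4.22 ± 0.42). ID2 rose 17.2-fold, from 5.80 to 9.90 (4.11 ± 0.66, adjusted p = 0.00134), with rises between 3.59 and 4.93 in the 4 lines. MYC, the growth-promoting transcription factor, fell 15.1-fold (-3.92 ± 0.41). In all, 2601 genes rose and 2417 fell, and among the 1417 that changed at least 2-fold 292 rose and 1125 fell.

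Of 23 measured genes of the T-cell receptor and its signalling, 18 fell and 0 rose (18 and 1 adjusted over the list alone; median -1.76, adjusted p = 1.38e-10, and adjusted p = 0.104 with an estimated correlation). The median lay below that of all 10000 random lists of like level, whose middle 95% ran from -0.71 to 0.01. CD3E (-1.68 ± 0.20), CD3G (-2.26 ± 0.18), the kinase ZAP70 (-2.24 ± 0.26) and the Ras activator RASGRP1 (-2.10 ± 0.18) fell. T-cell surface markers gave 15 lower and 0 higher of 27 (16 and 0 adjusted over the list alone; median -0.696, adjusted p = 0.000336, and adjusted p = 0.212 with an estimated correlation). The lipid-presenting CD1D (-2.73 ± 0.25) and the recombinase RAG1 (-2.73 ± 0.28) were among them. RAG1, RAG2 and DNTT, recombination genes that the fixed list also holds, are not themselves surface markers. T-lineage transcription factors gave 15 lower and 2 higher of 24 (15 and 3 adjusted over the list alone; median -0.877, adjusted p = 5.12e-05, and adjusted p = 0.104 with an estimated correlation). TOX (-3.32 ± 0.23), MYB (-3.24 ± 0.39) and BCL11B (-2.75 ± 0.17) fell. Within the lines without and with the 28S rise, the medians were -1.88 and -1.84 for the receptor list, -0.50 and -0.81 for the surface markers, and -0.93 and -0.78 for the transcription factors.

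ALCL-associated genes gave 8 higher and 2 lower of 30 (7 and 2 adjusted over the list alone). The list did not pass by camera with the preset correlation (median 0.378, adjusted p = 0.0856) or with an estimated correlation (adjusted p = 0.383). Fry called the list, as higher (adjusted p = 0.00958). Its median stood at percentile 96.86 of random lists of like level, inside the range of 0.0949 to 0.384 defined as for the receptor list. LGALS1 rose 7.57-fold, from 6.68 to 9.61 (2.92 ± 0.29), JUN by 1.92 ± 0.24 and CLU by 1.53 ± 0.37, the last with an adjusted p of 0.14 under spike centring. ANXA1, a phospholipid-binding protein, fell (-3.14 ± 0.48). ALK rose by 0.61 ± 0.22, only just past the threshold, and lost its call in 15 of 25 alternatives (adjusted p up to 0.908). TNFRSF8 was not called (-0.69 ± 0.32, adjusted p = 0.104, and 0.0321 without FE-PD). AP-1 and immediate early genes rose, 12 against 1 that fell of 22 (14 and 1 adjusted over the list alone; median 0.568, adjusted p = 0.00265, and adjusted p = 0.212 with an estimated correlation), and this median was -0.11 against -0.54 for all genes when arrays were centred on the spikes. IER3, an early response gene, rose by 2.33 ± 0.33. The list medians without and with the 28S rise were 0.30 and 0.38 for the ALCL-associated genes and 0.60 and 0.66 for the AP-1 list.

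Cancer-testis antigens, normally restricted to germ cells, gave 16 higher and 0 lower of 25 (17 and 0 adjusted over the list alone; median 0.612, adjusted p = 1.14e-05, and adjusted p = 0.0641 with an estimated correlation). MAGEA6 rose by 3.20 ± 0.41 and SSX1 by 3.13 ± 0.27. Germline genes gave 7 and 0 of 19 (12 and 0 adjusted over the list alone; median 0.494, adjusted p = 0.00448, and adjusted p = 0.212 with an estimated correlation). DAZL, a germ-cell RNA-binding protein, rose 12.3-fold (3.62 ± 0.43). Neuronal genes gave 17 and 0 of 31 (17 and 0 adjusted over the list alone; median 0.492, adjusted p = 0.000124, and adjusted p = 0.212 with an estimated correlation). The tubulin TUBB2A rose by 3.24 ± 0.28. Histone genes gave 26 and 2 of 33 (28 and 2 adjusted over the list alone; median 0.663, adjusted p = 1.88e-06, and adjusted p = 0.274 with an estimated correlation). The linker histone H1-2 rose 13.8-fold (3.79 ± 0.49) and the core histone H2BC12 by 2.80 ± 0.36. Spike centring moved the median of all genes from 0.14 to -0.54, and these 4 list medians with it to below 0, each still above that of all genes. In the lines without and with the 28S rise the medians were 0.57 and 0.66 for cancer-testis antigens, 0.27 and 0.47 for germline genes, 0.40 and 0.57 for neuronal genes, and 0.73 and 0.72 for histones. Metallothioneins, which bind metals, gave 10 and 0 of 11 (10 and 0 adjusted over the list alone; median 1.2, adjusted p = 0.00146, and adjusted p = 0.289 with an estimated correlation). Their medians were 1.95 without and 0.52 with the 28S rise. The fixed list also holds MTF1 and SLC30A1, which are not themselves metallothioneins.

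Markers of other cell types also gave more members higher than lower in T-cell lines. These were mesenchymal and matrix genes (13 and 1 of 29, 13 and 1 adjusted over the list alone; median 0.414, adjusted p = 0.00576, and adjusted p = 0.212 with an estimated correlation), NK-cell markers (6 and 0 of 13, 6 and 0 adjusted over the list alone; median 0.51, adjusted p = 0.00941, and adjusted p = 0.464 with an estimated correlation), erythroid and megakaryocyte markers (7 and 0 of 20, 7 and 0 adjusted over the list alone; median 0.276, adjusted p = 0.00892, and adjusted p = 0.464 with an estimated correlation) and epithelial genes (6 and 0 of 20, 1 and 0 adjusted over the list alone; median 0.28, adjusted p = 0.0462, and adjusted p = 0.336 with an estimated correlation). Among random lists of like level these medians stood at percentiles 99.42, 99.02, 52.18 and 59.29 in that order. Spike centring took them to -0.268, -0.173, -0.406 and -0.402, above the -0.54 of all genes. Without and with the 28S rise they were 0.333 and 0.447, 0.242 and 0.738, 0.215 and 0.359, and 0.227 and 0.333. B-cell and myeloid markers did not pass (adjusted p = 0.336 and 0.183).

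Cell-cycle and mitosis genes gave 29 lower and 1 higher of 39 (31 and 1 adjusted over the list alone; median -1.37, adjusted p = 6.95e-10, and adjusted p = 0.336 with an estimated correlation). CCNA2, which encodes cyclin A2, changed by -1.55 ± 0.19. DNA replication genes gave 25 and 1 of 37 (26 and 1 adjusted over the list alone; median -0.715, adjusted p = 6.35e-09, and adjusted p = 0.212 with an estimated correlation). The helicase subunit MCM7 changed by -1.72 ± 0.16. MYC and ribosome biogenesis genes gave 18 lower and 1 higher of 24 (20 and 1 adjusted over the list alone; median -0.86, adjusted p = 3.52e-07, and adjusted p = 0.254 with an estimated correlation). Medians without and with the 28S rise were -0.89 and -1.73 (cell cycle), -0.605 and -0.78 (replication), and -0.65 and -1.12 (ribosome). Highly expressed genes had lower changes in general. Among random lists of like level the cell-cycle median stood at percentile 0, the ribosome list at 1.74 and the replication list at 6.82. The cell-cycle inhibitor CDKN1A rose by 1.44 ± 0.29. DNMT1, the target of the demethylating drug, and HDAC1 were not called (-0.64 ± 0.24 and -0.31 ± 0.18, adjusted p = 0.0578 and 0.177), though DNMT1 was in 8 of 25 alternatives (adjusted p down to 0.00253) and HDAC1 in 2 (down to 0.0102). Among the 8 largest falls were also the interferon-inducible IFI16 (-3.87 ± 0.21) and NMI (-3.78 ± 0.28), the lymphocyte GTPase GIMAP6 (-3.87 ± 0.51), the integrin ITGA4 (-3.83 ± 0.42) and the immunoproteasome subunit PSMB10 (-3.38 ± 0.36).

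The share of calls that rose was 51.8% as deposited, 79.3% with arrays centred on housekeeping genes, 2.1% on the spikes and 39.3% on the array median. The median of all genes was 0.14, 0.495, -0.54 and 0.05 in that order. The count of 5018 fell to 886 with the ACTB 3' minus 5' difference as a covariate and 2025 with the 28S signal as one. It was 1496 in the 2 T-cell lines without the 28S rise and 3019 without JB6 and Molt-4, and 2520 or 2572 when Molt-3 or Molt-4 was left out.

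**Figure D3:**
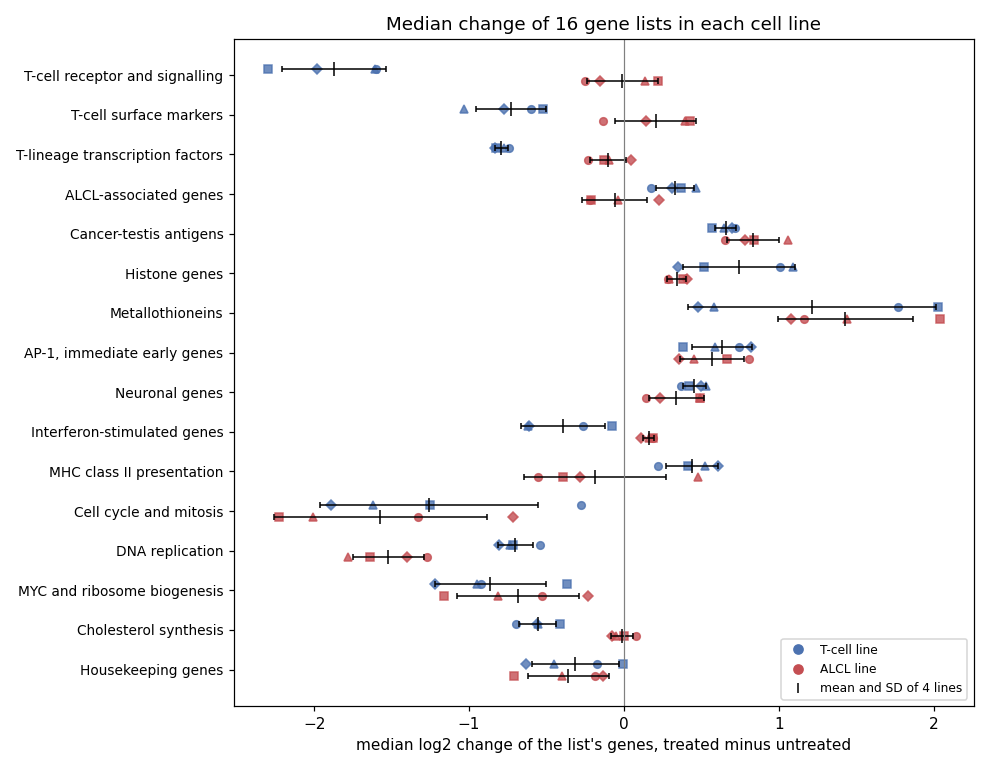
Median log2 change (x axis, treated minus untreated) of 16 gene lists in each T-cell line (blue) and ALCL line (red), with the mean and SD of the 4 lines as black bars. The receptor list lies between -2.3 and -1.6 in T-cell lines and near 0 in ALCL lines.

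In ALCL lines cancer-testis antigens rose, and DNA replication genes (adjusted p = 0.104 with an estimated correlation) and the CD30 gene TNFRSF8 fell. SPP1, which encodes osteopontin, rose 32.9-fold (5.04 ± 0.23, n = 4, adjusted p = 5.46e-06), TKTL1 29.8-fold (4.90 ± 0.40) and AGT, angiotensinogen, 28.8-fold (4.85 ± 0.49). TNFRSF8 fell 9.51-fold, from 11.48 to 8.23 (-3.25 ± 0.32, adjusted p = 0.000234). IL2RA, the interleukin-2 receptor alpha chain, fell (-3.08 ± 0.31), and the pseudogene CMAHP fell 15-fold (-3.91 ± 0.27). In all, 962 genes rose and 1604 fell, and among 1004 that changed at least 2-fold 275 rose and 729 fell.

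Cancer-testis antigens rose, 16 against 0 of 25 (18 and 0 adjusted over the list alone; median 0.685, adjusted p = 8.16e-08, and adjusted p = 0.023 with an estimated correlation). Of the 35 lists tested in ALCL lines, this was the only one called with an estimated correlation. MAGEA6 rose by 3.59 ± 0.41. AP-1 and immediate early genes gave 9 and 0 of 22 (11 and 0 adjusted over the list alone; median 0.616, adjusted p = 0.000203, and adjusted p = 0.251 with an estimated correlation). FOS (3.27 ± 0.35), the phosphatase DUSP1 (2.63 ± 0.30) and the mRNA-decay factor ZFP36 (1.87 ± 0.17) rose. Metallothioneins gave 7 and 0 of 11 (10 and 0 adjusted over the list alone; median 1.41, adjusted p = 6.72e-05, and adjusted p = 0.352 with an estimated correlation). MT1X rose by 2.55 ± 0.36 and MT2A by 2.22 ± 0.32. Histone genes gave 10 and 2 of 33 (10 and 2 adjusted over the list alone; median 0.284, adjusted p = 0.00369, and adjusted p = 0.534 with an estimated correlation), and this median was -0.32 against -0.516 for all genes under spike centring. H1-2 rose by 3.55 ± 0.49. In the 1 line without and the 3 with the 28S rise the medians were 0.78 and 0.74 for cancer-testis antigens, 0.35 and 0.64 for the AP-1 list, 1.08 and 1.51 for metallothioneins, and 0.41 and 0.32 for histones. DHRS2 (4.20 ± 0.42), the pentraxin NPTX2 (3.69 ± 0.37) and the protease inhibitor SLPI (3.45 ± 0.20) completed the 8 largest rises.

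Neuronal genes rose in ALCL lines too (10 and 1 of 31, 13 and 1 adjusted over the list alone; median 0.305, adjusted p = 0.000872, and adjusted p = 0.352 with an estimated correlation), and the effects on them did not differ detectably (adjusted p = 0.0969). Mesenchymal and matrix genes (8 and 1 of 29, 9 and 2 adjusted over the list alone; median 0.299, adjusted p = 0.0116, and adjusted p = 0.352 with an estimated correlation), epithelial genes (3 and 0 of 20, 3 and 0 adjusted over the list alone; median 0.326, adjusted p = 0.0118, and adjusted p = 0.367 with an estimated correlation), B-cell markers (1 and 0 of 17, 1 and 0 adjusted over the list alone; median 0.295, adjusted p = 0.0339, and adjusted p = 0.56 with an estimated correlation) and myeloid markers (4 and 0 of 24, 4 and 0 adjusted over the list alone; median 0.15, adjusted p = 0.0487, and adjusted p = 0.534 with an estimated correlation) passed as lists with the preset correlation, as did NF-kB target genes (7 and 1 of 25, 9 and 1 adjusted over the list alone; median 0.384, adjusted p = 0.00369, and adjusted p = 0.519 with an estimated correlation) and germline genes (3 and 0 of 19, 3 and 0 adjusted over the list alone; median 0.222, adjusted p = 0.0352, and adjusted p = 0.367 with an estimated correlation). Among random lists of like level these medians stood at percentiles 99.8, 100, 99.66, 94.14, 55.11, 99.98 and 88.95 in that order. Spike centring took them to between -0.455 and -0.221, above the -0.516 of all genes. Without and with the 28S rise they were 0.231 and 0.405, 0.261 and 0.285, 0.184 and 0.245, 0.171 and 0.353, 0.285 and 0.157, 0.569 and 0.359, and 0.16 and 0.24. NK-cell and erythroid markers did not pass (adjusted p = 0.471 and 0.0504).

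DNA replication genes fell in ALCL lines, 34 of 37 with 0 higher (35 and 0 adjusted over the list alone; median -1.43, adjusted p = 3.3e-29, and adjusted p = 0.104 with an estimated correlation). The middle 95% of random lists of like level ran from -0.56 to -0.07. MCM7 and MCM2, subunits of the replicative helicase, changed by -2.81 ± 0.16 and -2.38 ± 0.18, and TYMS, thymidylate synthase, by -3.30 ± 0.19, although its 2 probe sets differed in sign. Cell-cycle genes gave 28 lower and 0 higher of 39 (32 and 0 adjusted over the list alone; median -1.66, adjusted p = 2.16e-16, and adjusted p = 0.352 with an estimated correlation). AURKB, the mitotic kinase aurora B, changed by -2.83 ± 0.28 and CCNA2 by -2.21 ± 0.19. MYC and ribosome genes gave 15 lower and 1 higher of 24 (18 and 2 adjusted over the list alone; median -0.646, adjusted p = 3.12e-06, and adjusted p = 0.367 with an estimated correlation). The medians of the replication list without and with the 28S rise were -1.40 and -1.60, those of the cell-cycle list -0.72 and -1.84 and those of the ribosome list -0.235 and -0.75. CDKN1A rose by 1.55 ± 0.29, and DNMT1 fell (-1.49 ± 0.24).

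The receptor list did not pass in ALCL lines, with 1 higher and 3 lower of 23 (1 and 3 adjusted over the list alone; median -0.057, adjusted p = 0.415). The phosphatases PTPRC, or CD45 (-2.41 ± 0.32), and PTPN22 (-1.03 ± 0.12) were among those that fell. LCK and CD3E were not called (0.50 ± 0.22 and 0.25 ± 0.20, adjusted p = 0.133 and 0.392). The ALCL-associated list gave 2 higher and 6 lower of 30 (2 and 6 adjusted over the list alone, adjusted p = 0.393), with a median of 0.06 and a mean of -0.23. That median stood at percentile 98.93 of random lists of like level, above their middle 95% of -0.522 to 0.0175. Genes of like level thus had lower medians in general. BATF3, an AP-1 factor, fell (-1.59 ± 0.21), and LGALS1 was not called (0.12 ± 0.29, 95% interval from -0.52 to 0.77). ALK changed by -0.76 ± 0.22 (adjusted p = 0.0361), a call lost in 14 of 25 alternatives (adjusted p up to 0.577), among them without JB6 (0.156), SU-DHL-1 (0.164), Karpas 299 (0.0599) or Molt-3 (0.054). GAS1 (-3.36 ± 0.45), the calcium channel subunit CACNA2D3 (-3.35 ± 0.32), the cytokine IL26 (-3.23 ± 0.19) and the adhesion regulator CYTIP (-3.20 ± 0.46) were among the 8 largest falls.

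The count of 2566 was 1440 without the line block, 1432 without JB6, 1526 without SU-DHL-1 and 1338 without JB6 and Molt-4. It was 2351 in the ALCL lines with the 28S rise, 480 with the 28S signal as a covariate and 291 with the ACTB difference as one. The 3 lines without the rise gave 6, a value not comparable with these, since Karpas 299 is their 1 ALCL line and is assumed to vary like CCRF-CEM and Jurkat. The share of calls that rose was 37.5% as deposited, 79.3% with housekeeping and 3.57% with spike centring. The median of all genes was 0.09, 0.45 and -0.516.

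Whether the effect differed between the cell types was tested by the interaction. T-cell genes that fell in T-cell lines had higher effects in ALCL lines, with a difference of effects (ALCL minus T-cell) of 3.88 ± 0.31 for LCK (adjusted p = 0.000356), 1.93 ± 0.29 for CD3E (adjusted p = 0.116 under spike centring and 0.0626 under quantile normalization), 3.73 ± 0.23 for TRAT1, 3.42 ± 0.32 for TOX and 3.80 ± 0.31 for ADA. SPP1 (4.33 ± 0.33) and AGT (4.61 ± 0.70) also had the higher effect in ALCL lines, as did ITGA4, a call lost in 10 of 24 alternatives (adjusted p up to 0.607). LGALS1 had the higher effect in T-cell lines (-2.80 ± 0.41, adjusted p = 0.011, and 0.316 without the line block), and IL2RA (-3.66 ± 0.44), IL26 (-3.25 ± 0.27) and CACNA2D3 (-3.71 ± 0.45) had the lower effect in ALCL lines. TNFRSF8 differed by -2.56 ± 0.45 (adjusted p = 0.0214), a call lost in 6 of 24 alternatives (up to 0.293), among them without JB6 (0.0636), Molt-3 (0.0855) or Molt-4 (0.0732). GAS1, CYTIP and APOBEC3B also had the lower effect in ALCL lines, with calls lost in 6 of 24, 10 of 23 and 3 of 23 alternatives. ID2 was not called (-3.01 ± 0.93, adjusted p = 0.175), but was without FE-PD (-4.15 ± 0.30, adjusted p = 0.000426). In all 201 genes differed, 68 with the higher effect in T-cell lines and the others in ALCL lines.

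The receptor list had the higher effect in ALCL lines, 11 of 23 genes with 0 the other way (16 and 0 adjusted over the list alone; median 1.65, adjusted p = 2.38e-19, and adjusted p = 0.0695 with an estimated correlation). So had the surface markers, 7 and 0 of 27 (15 and 1 adjusted over the list alone; median 1.03, adjusted p = 2.34e-10, and adjusted p = 0.0771 with an estimated correlation). T-lineage transcription factors gave 4 and 0 of 24 (9 and 1 adjusted over the list alone; median 0.484, adjusted p = 1.72e-06, and adjusted p = 0.0695 with an estimated correlation). DNA replication genes had the lower effect in ALCL lines, 9 and 0 of 37 (23 and 0 adjusted over the list alone; median -0.817, adjusted p = 8.29e-20, and adjusted p = 0.0887 with an estimated correlation). The ALCL-associated genes had the higher effect in T-cell lines, 3 and 0 of 30 (11 and 2 adjusted over the list alone; median -0.627, adjusted p = 0.000158, and adjusted p = 0.12 with an estimated correlation). None of these 5 lists changed sign under the 5 scalings. The T-cell lists were lower and the ALCL-associated list higher in untreated ALCL lines, so starting level may enter these differences too. LCK in untreated ALCL lines left no room for a fall as large as in T-cell lines. The ALCL-associated list had medians of 0.378 in T-cell and 0.0583 in ALCL lines. Random lists of like level had medians of 0.241 and -0.212, so part of its difference goes with level. The effect on cancer-testis antigens did not differ detectably (median -0.0228, adjusted p = 0.916). The count of 201 was 62 without the line block, 67 without Molt-3, 88 without Molt-4 and 51 without JB6 and Molt-4. It was 223 in the lines with the 28S rise. It was 0 by limma in the 3 without it, where 1296 genes had an unadjusted p below 0.05 and the 1 ALCL line is assumed to vary like the 2 T-cell lines. The share of calls with the higher effect in ALCL lines was 66.2% as deposited and 76.6% under spike centring.

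The changes in both cell types nevertheless ran together across genes. Pearson's r between the mean changes was 0.728 and Spearman's rho 0.727 over 11963 genes, which are not independent replicates. The r between single lines of the 2 types was 0.346 to 0.673 over 16 pairs. Both cell types raised 615 genes (209 for independent lists) and lowered 1267 (324), and 31 were called in opposite directions. TKTL1, DHRS2, MAGEA6 and H1-2 were among the 8 largest rises in each. The r was 0.533 within the 3 lines without the 28S rise and 0.677 within the 5 with it.

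Treated T-cell lines were then compared with untreated ALCL lines, the comparison closest to the question of the series. GZMB was still 80.9-fold higher in ALCL lines (6.34 ± 0.38, n = 4 and 4), SERPINA1 73.3-fold and CLU 37.1-fold. ID2 (0.09 ± 0.96, adjusted p = 0.954), JUN (0.35 ± 0.42, adjusted p = 0.574) and ZAP70 (0.45 ± 0.51, adjusted p = 0.553) were not called. TNFRSF8 was 20.3-fold higher in ALCL lines (4.34 ± 0.24) and CD3E and LCK lower (-1.47 ± 0.24 and -2.32 ± 0.20). LGALS1 was higher by 2.48 ± 0.58 (adjusted p = 0.0208, and 0.0601 without JB6). TKTL1, DHRS2 and MAGEA6 were lower in ALCL lines (-5.18 ± 0.47, -4.64 ± 0.74 and -3.83 ± 0.66). In all 1088 genes were higher and 1055 lower.

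ALCL-associated genes were higher in ALCL lines as a list, 17 and 0 lower of 30 (19 and 0 adjusted over the list alone; median 2.01, adjusted p = 8.32e-14, and adjusted p = 0.00367 with an estimated correlation). TIMP1 differed by 4.79 ± 0.65 and IL1R2 by 5.07 ± 0.21. The receptor list no longer passed, with 3 higher and 5 lower of 23 (3 and 7 adjusted over the list alone; median -0.125, adjusted p = 0.529). Cytotoxic granule genes gave 6 higher and 1 lower of 14 (6 and 3 adjusted over the list alone; median 0.967, adjusted p = 0.00735, and adjusted p = 0.257 with an estimated correlation). PRF1 differed by 5.40 ± 0.28. Cancer-testis antigens were higher in the treated T-cell lines, 14 and 0 of 25 (15 and 0 adjusted over the list alone; median -0.707, adjusted p = 1.43e-05, and adjusted p = 0.257 with an estimated correlation), and this median was 0.32 against 0.93 for all genes under spike centring. MAGEA12 differed by -3.78 ± 0.69. GAS1 (5.62 ± 0.34) and TNS3 (4.83 ± 0.50) were higher in ALCL lines, and IGFBP2 (-4.11 ± 0.38), DAZL (-3.70 ± 0.47), TSC22D1 (-3.62 ± 0.62) and the pseudogene DPY19L2P2 (-3.75 ± 0.51) lower. The share of calls higher in ALCL lines was 50.8% as deposited, 14% with housekeeping and 98.3% with spike centring. The median of all genes was -0.09, -0.51 and 0.93. The count of 2143 was 1422 without JB6, 1234 without Molt-3, 960 without JB6 and Molt-4, and 4864 with housekeeping centring. It was 354 in the lines without the 28S rise and 1911 in those with it.

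Among the 1048 genes that separated the untreated cell types, 80.4% moved in T-cell lines toward the ALCL level, and 506 were called toward it and 58 away. LCK, LGALS1, ID2, JUN and CLU were among those called toward it and DNMT3B among those called away, and TNFRSF8, not called, was lower in all 4 treated T-cell lines and so farther from the ALCL level. Some of these genes were chosen from knowledge of this field and this study, so their direction is not independent evidence. The slope of the change on the starting difference was 0.334, against 0.0191 (58.9% of genes) in simulations of unchanged lines, which share the untreated arrays in the same way. The covariance was 0.954 against 0.0907. With the T-cell lines split so that no array was shared, the slope was 0.251 (78.3% of genes) against 0.000547, and the covariance 1.62 against 0.00536. The 2 of these 6 splits that keep Molt-3 and Molt-4 together gave slopes of 0.283 and 0.178 (81.4% and 67.6% of genes) and covariances of 2.08 and 0.676. The 668 genes higher in T-cell lines had a slope of 0.54, with 391 called toward the ALCL level and 21 away. The 380 genes higher in ALCL lines had a slope of 0.144, with 115 and 37. Slopes of single lines were 0.24 (CCRF-CEM), 0.31 (Jurkat), 0.37 (Molt-3) and 0.416 (Molt-4), and the slope in ALCL lines was -0.103. In ALCL lines the 380 genes had a slope of -0.194, with 114 called toward the T-cell level and 32 away, and the 668 genes one of -0.00408, with 58 and 129. Under spike centring the T-cell slope was 0.111, and it was 0.144 within the 3 lines without the 28S rise and 0.382 within the 5 with it. In those 3 lines the starting difference rests on 1 ALCL line, so 0.144 is not comparable with 0.334. On the 1048 genes the T-cell lines without the rise, CCRF-CEM and Jurkat, had the slopes of 0.24 and 0.31 given above. Those with it, Molt-3 and Molt-4, had 0.37 and 0.416.

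**Figure D4:**
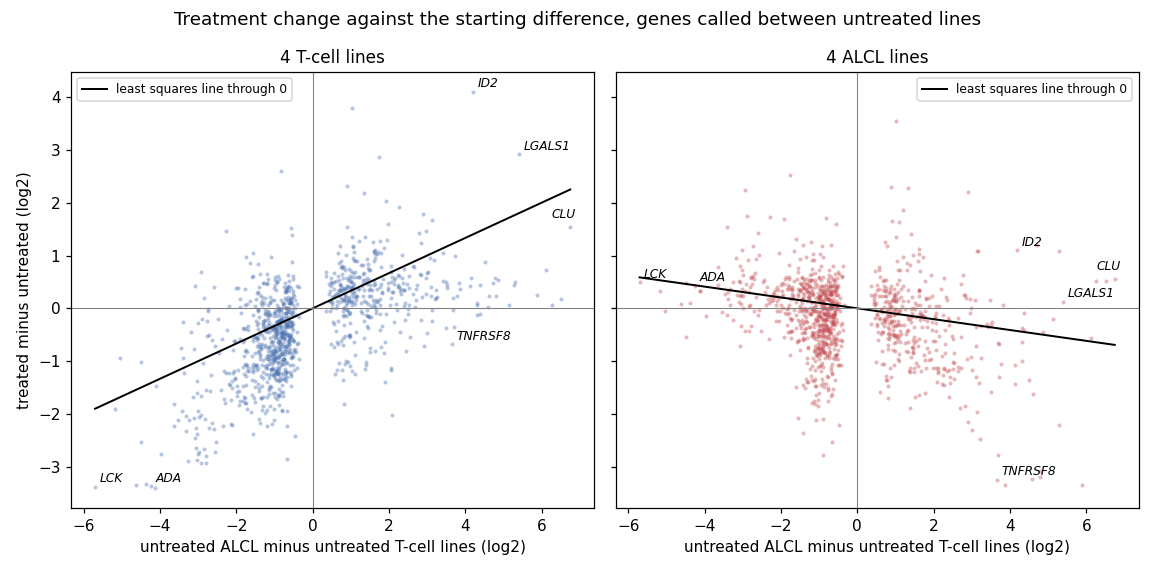
Mean treatment change (y axis, log2) against the untreated ALCL minus T-cell difference (x axis, log2) for 1048 genes called between the untreated cell types, in T-cell lines (left) and ALCL lines (right), each point a gene and the black line the least squares line through 0. The slope is 0.334 in T-cell lines and -0.103 in ALCL lines.

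Of the 1048 genes, 480 (45.8%) still differed in the same direction between untreated ALCL and treated T-cell lines. Unchanged lines sharing the ALCL arrays gave 75.9% in simulations, and independent lists 93.5 genes, and 27 genes differed in the opposite direction. The simulated share comes from noisier values and from the 627 genes called there in the mean, so it is a rough reference. The correlation of the whole profile with the untreated ALCL arrays did not rise, with a mean r of 0.889 untreated and 0.865 treated. The change was below 0 in 4 of 4 T-cell lines (-0.0243 ± 0.0118, SD). The exact sign-flip permutation test stood at the smallest p that 4 lines allow, which is above 0.05. Within the lines without the 28S rise the mean change was -0.0126. A comparison with untreated ALCL arrays also holds the change that treatment made in both cell types. With the treated ALCL arrays, treated T-cell lines had a mean r of 0.893 (Molt-4) to 0.902 (Jurkat).

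With both cell types treated, 162 genes were higher and 183 lower in ALCL lines. GZMB was 116-fold higher (6.85 ± 0.24, n = 4 and 4, adjusted p = 3.3e-06), SERPINA1 105-fold. AGT (5.30 ± 0.71) and SPP1 (4.87 ± 0.57) were now among the largest differences beside TIMP1 (5.87 ± 0.55), CLU (5.77 ± 0.57), SERPINB1 (5.44 ± 0.38) and IL1R2 (4.86 ± 0.43). LCK was lower in ALCL lines (-1.82 ± 0.20), as were IGFBP2 (-4.15 ± 0.37), ITM2A (-3.01 ± 0.37), TSPAN7 (-2.95 ± 0.30), PNMA2 (-2.74 ± 0.45) and the kinase PRKCB (-2.71 ± 0.32). HMGB2 was lower too, a call lost in 5 of 22 alternatives (adjusted p up to 0.508). CD3E differed by -1.22 ± 0.21 (adjusted p = 0.0156), a call lost in 6 of 22 alternatives (up to 0.831), among them under spike centring (0.831) and without CCRF-CEM (0.0531) or Molt-3 (0.0672). TNFRSF8 was not called (1.09 ± 0.39, adjusted p = 0.199). Of the 1048 genes that differed before treatment, 187 still differed in the same direction, against 15.4 for independent lists.

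ALCL-associated genes gave 8 higher and 0 lower of 30 (18 and 0 adjusted over the list alone; median 1.16, adjusted p = 1.12e-21, and adjusted p = 0.0385 with an estimated correlation). DNA replication genes were lower in treated ALCL lines, 15 and 0 of 37 (32 and 0 adjusted over the list alone; median -1.17, adjusted p = 2.83e-23, and adjusted p = 0.108 with an estimated correlation). Cell-cycle genes were lower too, 5 and 0 of 39 (11 and 0 adjusted over the list alone; median -0.914, adjusted p = 1.47e-11, and adjusted p = 0.237 with an estimated correlation). The checkpoint gene MAD2L1 differed by -2.53 ± 0.36 and the mitotic kinesin KIF11 by -2.44 ± 0.33. The receptor list gave 2 lower and 0 higher of 23 (6 and 0 adjusted over the list alone; median -0.338, adjusted p = 0.00179, and adjusted p = 0.229 with an estimated correlation), and this median was 0.08 under spike centring. That centring moved the median of all genes from -0.03 to 0.386 and the share of calls higher in ALCL lines from 47% to 92.8%. The count of 345 was 203 without CCRF-CEM, 130 without Molt-3, 217 without Molt-4 and 156 without JB6 and Molt-4. It was 152 in the lines without the 28S rise and 98 in those with it, and 536 with housekeeping centring.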

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

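Of the tests below, those on the narrower range of the treated arrays, on movement in genes of 1 direction, and the alternatives without JB6 and Molt-4 and within lines of like ribosomal signal, were chosen only after the data had been seen. Single lines far from the other 3 of their type were sought in 108 sets of 4 values, of which chance gives about 5.4, and 4 were found. ID2 changed by 4.54 in FE-PD and by -0.153 to 0.0325 in the other ALCL lines, where its untreated level was already 10.2 to 11.7 against 6.79 in FE-PD. ZAP70 changed by 0.465 in SU-DHL-1 and by -1.12 to -0.972 in the other ALCL lines. The median change of the NF-kB target genes was 0.158 in CCRF-CEM and 0.353 to 0.391 in the other T-cell lines. The ACTB 3' minus 5' difference changed by 1 in Molt-4 and by 0.384 to 0.471 in the other T-cell lines.

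The effect of treatment differed between the cell types for 201 genes by the interaction test. Among the genes fixed in advance the ALCL minus T-cell differences of effect were -2.80 for LGALS1, -2.56 for TNFRSF8, 1.93 for CD3E and 3.88 for LCK. Each of these genes also differed between the untreated cell types, so starting level may enter. LCK stood at 5.71 to 6.29 in untreated ALCL lines, which left no room for its T-cell change of -3.38. LGALS1 stood at 11.3 to 12.6 there, which left little room for its T-cell rise of 2.92. TNFRSF8 stood at 7.09 to 7.21 in treated T-cell lines, so a floor may have limited its fall there. For LCK, LGALS1 and TNFRSF8 the interaction therefore cannot tell a different response from a limit of range. The effect also differed for 12 gene lists by camera with the preset correlation, for 7 by fry and for 0 with an estimated correlation. In control probe sets that no comparison uses, the mean rise with treatment over 8 lines was 4.19 for 28S ribosomal RNA and 0.638 for Alu repeats.

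The first pattern weighed is the fall of the T-cell receptor genes in treated T-cell lines, a list call that is lost with an estimated correlation (adjusted p = 0.104), with 17 of its members lower without JB6 and Molt-4. A narrower range of values on treated arrays would lower any highly expressed genes, but the list median of -1.76 lay below all 10000 random lists of like level. Under the 5 scalings the highest list median was -1.40. In CCRF-CEM and Jurkat, which lack the ribosomal signal, the mean of the line medians was -1.95 against -1.79 in Molt-3 and Molt-4, so a labelling or RNA difference marked by that signal is argued against too. RNA quality was not weighed for this list, and the ACTB 3' minus 5' difference rose in each T-cell line, by 0.384 (Jurkat) to 1 (Molt-4). A loss of T-cell gene expression under the treatment may be biological, a hypothesis that these data raised. With 1 array per line and condition it cannot be separated from lower RNA quality, or from death or selection of cells during 6 days.

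The second pattern is the movement of T-cell lines along the starting difference. Shared untreated arrays do not account for it, since the slope was 0.251 with no array shared, against at most 0.0134 in the middle 95% of simulations, and 0.231 (0.283 and 0.178) in the 2 splits that keep Molt-3 and Molt-4, from 1 patient, together, against at most 0.0129. Relative to uncalled genes of like level it was 0.171 (0.156 in those 2 splits), so the narrower range may account for part of the slope but not for all of it. Over all genes the split slope in ALCL lines was -0.0401, toward the T-cell lines but small beside the T-cell one of 0.251, and convergence of both cell types is argued against by 0.0624 (SD 0.0772 over 6 splits) for genes higher in T-cell lines, where the T-cell split slope was 0.424. For genes higher in ALCL lines the ALCL split slope of -0.107 (SD 0.0336) was as large as the T-cell one of 0.101. It lay below the middle 95% of simulated unchanged lines, -0.01 to 0.0121. Over these genes the values met the bound set, after the data were seen, for convergence of both cell types. This ALCL slope was not matched on level, so the narrower range may enter it. Whether the fall of T-cell genes is a step toward ALCL or a loss of T-cell features only stays open.

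The third pattern is the narrower range itself. It does not rest on JB6 and Molt-4, since all of the other 6 lines also had a narrower treated array, the least by -0.0231 in FE-PD. That restates the narrowing in 8 of 8 lines given above and is no separate test. Lower RNA quality cannot be told apart from treatment, because over the 8 lines the change in SD and in the ACTB 3' minus 5' difference had r = -0.65 (exact permutation p = 0.0806, the 1 such relation computed) and rho = -0.595 (exact p = 0.132), and r = -0.514 without the 2 farthest lines, Karpas 299 and JB6. A biological narrowing, by a rise of silent genes and a fall of abundant ones, was not tested separately and stays open.

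For each count of genes, 1 of 35 splits, the real one, gave as many. The real count and the highest of the other splits were 5018 and 892 for treatment in T-cell lines, 2566 and 2220 in ALCL lines, 201 and 2 for the interaction, 1048 and 5 between untreated cell types, 2143 and 0 between untreated ALCL and treated T-cell lines, and 345 and 1 between treated ones. For treatment, only 8 splits part all pairs of a line's arrays, as the real one does, and the highest other of these gave 0 genes in both cell types. The others could not be fitted or part only 2 pairs, and under the line block their counts rest on those 2 lines alone. In the highest, 892 and 2220, these were Molt-3 and Molt-4, and JB6 and SU-DHL-1, parted by treatment. Those 2 counts therefore hold the treatment effect in fewer lines and are no reference for chance. For the interaction and between cell types, only 15 splits keep Molt-3 and Molt-4, from 1 patient, in 1 group as the real one does, with highest others of 2, 5, 0 and 1, and the other splits treat both as independent lines. Neither 8 nor 15 splits are enough for a share under 0.05.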

How the results depend on the processing

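Alternatives that left out JB6 and Molt-4, used only lines of like 28S signal, added a covariate, scaled to 1 mean and SD or matched on level were chosen after the data were examined. The cause was not tested for the differences below unless fewer arrays or genes are part of the alternative. Counts are given in the order treatment in T-cell lines, treatment in ALCL lines, interaction, untreated, untreated ALCL against treated T-cell, and treated, and a comparison not named stayed within 1.5 times its main count of 5018, 2566, 201, 1048, 2143 or 345.

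Without the line block that pairs a line's arrays, 3642, 1440 and 62 genes were called, with 20, 18 and 12 lists, and with line as a random block 585 in the last. Without the block CDKN1A was not called in T-cell (adjusted p = 0.0522) or ALCL lines (0.0726), nor in ALCL lines BATF3 (0.0568), and 16 of 130 values of single genes lost their call. Testing every probe set gave 8607, 4072, 1625 (untreated) and 3565 (untreated against treated). Spike centring gave 3006 and 64 (interaction), and housekeeping centring 4864 and 536 for the last 2. Array weights gave 8741, 824 (interaction), 1913, 4366 and 1216. A 2-fold minimum gave 1417, 1004, 599 (untreated) and 1163. Averaging Molt-3 and Molt-4 gave 2646, 74 (interaction), 472 and 181 (treated). Without JB6 and Molt-4 there were 3019, 1338, 51, 334, 960 and 156. The ACTB covariate gave 886 and 291, and the 28S covariate 2025 and 480. Lines without the 28S rise, with 1 ALCL line assumed to vary like the 2 T-cell lines, gave 1496, 6, 0, 111, 354 and 152 (the 0 by limma, with 1296 at an unadjusted p below 0.05), and lines with it 689 (untreated) and 98 (treated).

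Leaving out 1 line gave 2520 to 5493, 1432 to 2648, 67 to 195, 455 to 1195, 1234 to 2102 and 130 to 348 genes, lowest without Molt-3 except in ALCL lines (JB6). The slope of movement was 0.291 to 0.353, the profile correlation change -0.0276 to -0.0186, the agreement of effects 0.688 to 0.731 and the ACTB change 0.526 to 0.699. The slope was 0.251 with lines split, 0.111 under spike centring and 0.171 split and matched on level. It was 0.144 in lines without the 28S rise, where the starting difference rests on 1 ALCL line. On the 1048 genes the T-cell lines without the rise, CCRF-CEM and Jurkat, had slopes of 0.24 and 0.31. The profile change was -0.0640 without the lowest 40% of genes, and the agreement 0.533 in lines without the 28S rise.

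With an estimated correlation camera called 0, 1, 0, 5, 1 and 1 lists against 21, 17, 12, 20, 18 and 18 with the preset one, with 4 (T-cell) and 7 (interaction) at an unadjusted p below 0.05, and fry called 26, 18, 7, 15, 15 and 15. Of 5368 values of single genes over the alternatives, from 229 genes and comparisons, 4991 kept direction and side of the threshold, 276 lost their call, most often (97) in the lines without the 28S rise, and 100 gained one. ALK in T-cell lines, which lost its call in 14 others of 25 alternatives, went from 0.61 to -0.0743 under spike centring, which lowers the mean change of any gene there by 0.682. The arrays have no detection calls here, so what signal over background limits is unknown.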

Other observations

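Immune genes outside the T-cell receptor also moved in T-cell lines. Interferon-stimulated genes gave 17 lower and 4 higher of 40 (17 and 6 adjusted over the list alone; median -0.418, adjusted p = 0.00276, and adjusted p = 0.224 with an estimated correlation), with the membrane protein IFITM1 at -2.62 ± 0.16 and the transcription factor IRF1 at -1.14 ± 0.11, and medians of -0.23 in the lines without and -0.55 in those with the 28S rise. In ALCL lines they gave 9 higher and 6 lower (adjusted p = 0.744), with IFI27 at 2.06 ± 0.24, and the effects differed (3 higher and 0 lower in ALCL lines, 11 and 1 adjusted over the list alone; median 0.475, adjusted p = 7.96e-07, and adjusted p = 0.0887 with an estimated correlation). The immunoproteasome subunits PSMB8 (-3.31 ± 0.29) and PSMB10 fell in T-cell lines, and PSMB10 in ALCL lines (-2.72 ± 0.36). The MHC class I list they belong to had a median of -0.225 and a mean of -0.782 in T-cell lines, 6 lower and 1 higher of 15 (6 and 3 adjusted over the list alone; adjusted p = 0.0288, and adjusted p = 0.437 with an estimated correlation), and this median turned positive under housekeeping centring, quantile normalization and scaling to 1 mean and SD. It was -0.035 in the lines without and -0.315 in those with the 28S rise, and stood at percentile 90.67 of random lists of like level, so genes of like level had lower medians in general.

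Cholesterol synthesis genes fell in T-cell lines, 7 of 14 with 1 higher (9 and 2 adjusted over the list alone; median -0.656, adjusted p = 0.00248, and adjusted p = 0.212 with an estimated correlation), with the prenyl synthase FDPS at -2.11 ± 0.17 and HMGCS1 at -1.63 ± 0.23, and medians of -0.67 without and -0.585 with the 28S rise. That median stood at percentile 13.45 of random lists of like level, within their middle 95% of -0.874 to 0.0252. The effects differed between cell types (median 0.524, adjusted p = 2.23e-05, and adjusted p = 0.0887 with an estimated correlation). Before treatment the list was lower in ALCL lines, 6 of 14 with 0 higher (9 and 0 adjusted over the list alone; median -0.895, adjusted p = 4.97e-06, and adjusted p = 0.158 with an estimated correlation), with SQLE at -1.44 ± 0.18 and IDI1 at -1.44 ± 0.22. Imprinted genes rose in T-cell lines, 7 of 24 with 3 lower (7 and 3 adjusted over the list alone; median 0.296, adjusted p = 0.0323, and adjusted p = 0.212 with an estimated correlation), with MEST at 1.49 ± 0.12 and PEG10 at 1.66 ± 0.26, a median that was -0.39 against -0.54 for all genes under spike centring, was 0.24 without and 0.40 with the 28S rise and stood at percentile 79.8 of random lists of like level. Housekeeping genes, as a list, fell in T-cell lines, 9 and 0 of 22 (9 and 0 adjusted over the list alone; median -0.327, adjusted p = 0.0059, and adjusted p = 0.464 with an estimated correlation), which turned to 0.23 with 1 mean and SD per array and stood at percentile 86.66 of random lists of like level, and the median was -0.14 in lines without and -0.51 in lines with the 28S rise. In ALCL lines imprinted genes (6 higher and 1 lower of 24, 6 and 1 adjusted over the list alone; median 0.212, adjusted p = 0.0181, and adjusted p = 0.251 with an estimated correlation), the MHC class I list (0 higher and 6 lower of 15, 0 and 6 adjusted over the list alone; median -0.158, adjusted p = 0.0116, and adjusted p = 0.484 with an estimated correlation) and housekeeping genes (0 higher and 4 lower of 22, 0 and 2 adjusted over the list alone; median -0.328, adjusted p = 0.00329, and adjusted p = 0.536 with an estimated correlation) passed in the same directions as in T-cell lines, at percentiles 83.63, 89.95 and 67.01 of random lists of like level, and the MHC class I median turned to 0.204 under housekeeping centring, 0.0105 under quantile normalization and 0.178 with 1 mean and SD per array. Under spike centring the imprinted median was -0.393 against -0.516 for all genes, and housekeeping centring sets the housekeeping list near 0 by construction (0.0331). Over all genes the median change in T-cell lines went with level, from 0.21 and 0.28 in the 2 lowest of 5 equal bins of mean level over all arrays to -0.11 and -0.36 in the 2 highest.

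Of 3105 genes called in T-cell lines and not in ALCL lines, the effects were shown to differ for 99. Among the enzymes the treatment is aimed at, deacetylases gave 8 higher and 3 lower of 17 in T-cell lines (8 and 3 adjusted over the list alone, adjusted p = 0.399), with HDAC4 at -2.50 ± 0.27. The DNA methylation machinery gave 1 higher and 5 lower of 12 (1 and 7 adjusted over the list alone, adjusted p = 0.0825), with DNMT3B, a DNA methyltransferase, at 0.97 ± 0.14. Cyclin-dependent kinase inhibitors and growth arrest genes gave 7 higher and 1 lower of 19 (7 and 1 adjusted over the list alone, adjusted p = 0.0708), with TXNIP, the thioredoxin-binding protein, at 1.76 ± 0.26 and CDKN1B at -1.77 ± 0.32. None of these 3 lists passed by camera with the preset correlation. Fry called each of them, with adjusted p = 0.00301 (deacetylases, higher), 0.0102 (methylation machinery, lower) and 0.00958 (growth arrest genes, higher).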
